A study of Homo sapiens with 6 samples.

How the data were processed

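RNA-seq was measured in 6 libraries of MDA-MB231 cells, 2 each for a control siRNA, siL1 and siL2, where siL1 and siL2 are different siRNAs against LSD1. The cells grew in medium with 10% serum, were transfected with a lipid reagent, and total RNA was made into libraries by standard Illumina procedures per the labels. Per the labels the authors aligned reads with TopHat 1.3.3 to hg19, counted them per gene with HTSeq and compared groups with DESeq; the settings, annotation release and strand setting are not given. One deposited table held, per gene symbol, the raw count of each library, with no normalization. It also held the authors' fold change as a linear ratio of each siRNA over the control, and the authors' adjusted p-value of each comparison. The table had 23368 gene symbols, of which 5745 had 0 counts in all 6 libraries. The reads themselves were not analysed here.

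The libraries held 22047738 to 26765079 counts, with 15624 to 16065 genes detected, and the 10 most abundant genes took 3.00% to 3.10% of the counts. A count of 3, the limit that a count of 0 allows, corresponded to 0.112 to 0.136 CPM. This floor covers counting error only. The Wilson and exact intervals on shares are over genes, and the bootstrap intervals on medians are over list members. Because the table is summed per gene symbol, reads shared between paralogs, such as ribosomal protein, histone and HLA genes, cannot be followed.

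Counts were analysed with R 4.3.3, edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr by group (13322 tested, 10046 left out), scaled by TMM and fitted with glmQLFit with group as the only term over all 6 libraries, with 3 residual degrees of freedom. Comparisons were siL1 and siL2 each against the control, the mean of both against the control, and siL2 against siL1. Each used glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The common biological coefficient of variation was 3.72%. SDs are over the CPM of the 2 libraries of a group, and SEs are of the log2 fold change.

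Gene lists were tested with limma's camera at a preset correlation of 0.01 on log2 CPM (prior count 2), Benjamini-Hochberg adjusted over the lists of a comparison, and again with an estimated correlation. Failing with an estimated correlation does not by itself show correlated members, since lists with an estimate below the preset also failed. Of 38 lists fixed from general knowledge, with 1317 members of which 1302 were in the table, 37 had at least 5 tested members; of 13 mitochondrially encoded genes 0 were in the table. KDM1A was left out of every list. Counts of members past the threshold are given over all genes tested and adjusted over the list alone. Overlap and similarity of the siRNA effects were set beside the counts that independent lists would share and beside 20 simulations of unchanged groups against shared controls.

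Named genes were KDM1A; the 10 genes with the largest rise and the 10 with the largest fall per comparison (5 and 5 for siL2 against siL1) among those past the threshold, with a mean of at least 5 CPM and with groups that did not overlap; up to 4 members per list with the smallest p in the mean comparison; and MMP1, MMP9, ESRRA, CDH1, VIM, SNAI1, SNAI2, ZEB1, CDKN1A, MKI67 and IFIT1. Those named in the text are taken from these. KDM1A itself was among the 10 largest falls, so 9 others remained.

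3' UTR heptamers were scanned in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3; figures used matplotlib 3.10.9. The 3' UTRs were taken from GENCODE v29 on GRCh38, while the counts were made on hg19, and were joined by gene symbol; 89.0% of the tested genes had a matching symbol and 85.3% a 3' UTR of at least 50 bases. The scan took 10639 genes with a mean of at least 1 CPM and 15777 heptamers present in at least 100 genes. For each heptamer a z compared the change specific to a group between genes with and without it, after regression on 3' UTR length, GC content and mean CPM, beside 50 shuffles of the changes. A gene without an annotated 3' UTR counted as not searched. The siRNA sequences were not known.

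Calls were tested on simulated data with 50 planted genes per fold change. At a log2 change of 0.5 the test found 42 of 50 with siL1 and 39 of 50 with siL2, and at 1 it found 47 and 44, with 9 false calls each among 13214 genes. A planted list was found, with 0 of the other lists called. The simulated genes varied independently, so this cannot show how often the list test calls falsely where members are correlated. In the data the estimated correlation was 0.502 for ribosomal protein genes. As alternatives, each run alone, the size factors of DESeq2 and upper quartile scaling replaced TMM, the filter was dropped or set to 1 CPM in 2 libraries, and DESeq2 1.42.0 or limma-voom replaced the test. Further runs added the replicate number as a block, fitted only the groups compared, left out each library in turn, or required a log2 change of at least 1. Lists were also tested with fry. Alternatives for normalized values did not apply, because the table holds counts. Lists and similarity without genes that hold a heptamer, and the heptamer scan without genes whose 3' UTR holds an Alu core, were chosen after seeing the data.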

Results

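RNA-seq counts per gene were available for 6 libraries of MDA-MB231 cells, an established line of triple-negative breast cancer. The cells had been transfected with a control siRNA (siControl) or with either of 2 siRNAs, siL1 and siL2, against LSD1, the histone lysine demethylase encoded by KDM1A, with 2 libraries per group. The control libraries held 22047738 and 23624089 counts, the siL1 libraries 23510558 and 24649992, and the siL2 libraries 26765079 and 24638002. Values per gene are counts scaled to library size (CPM) and changes are log2 fold changes with edgeR quasi-likelihood tests, adjusted by Benjamini-Hochberg over 13322 genes. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these samples. The groups, comparisons, tests, gene lists and the rule for naming genes were set before the data were examined.

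KDM1A fell with both siRNAs. It stood at 158 and 165 CPM in the control libraries, 27.7 and 28.3 CPM with siL1, and 17.3 and 18.1 CPM with siL2. The group means were 162 ± 4.56, 28.0 ± 0.409 and 17.7 ± 0.570 CPM (SD, n = 2 each). KDM1A fell by 2.53 on the log2 scale with siL1 (SE 0.0538, adjusted p = 1.09e-11) and fell by 3.19 with siL2 (SE 0.0567, adjusted p = 2.16e-12). It was lower with siL2 than with siL1 (log2 difference -0.66, adjusted p = 4.36e-06). The authors' deposited fold changes for KDM1A were 0.174 with siL1 and 0.110 with siL2.

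**Figure D1:**
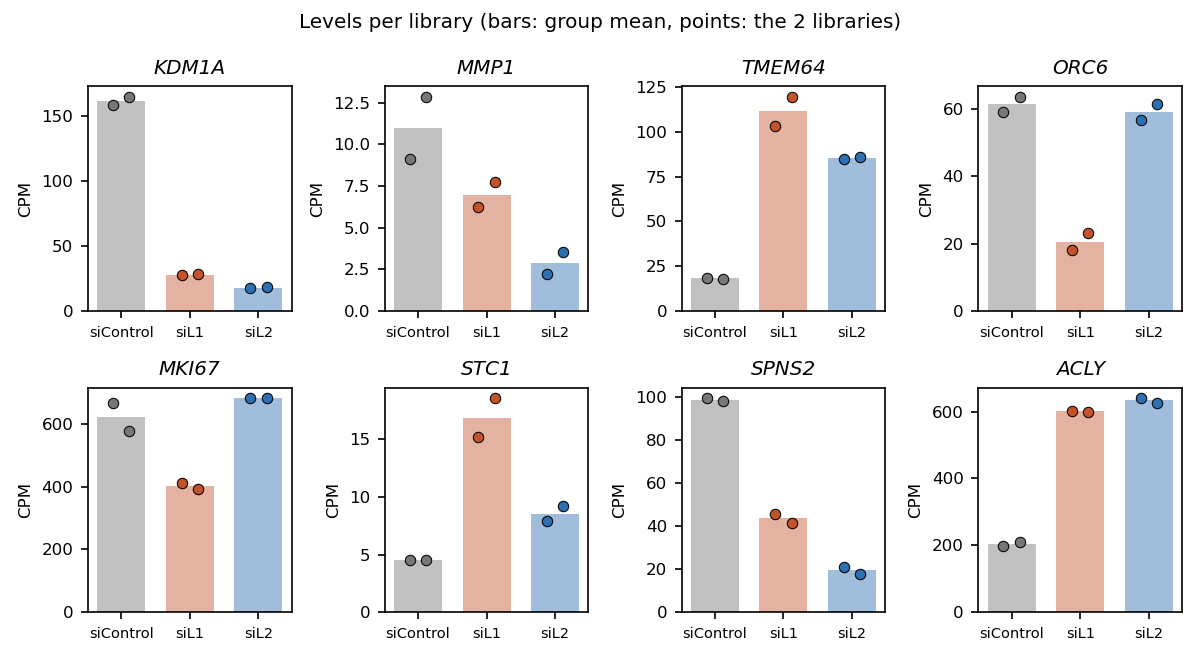
Level of 8 genes in CPM (vertical axis, linear and starting at 0) for the control siRNA, siL1 and siL2; bars are group means and points are the 2 libraries of each group. KDM1A fell from a mean of 162 CPM to 28.0 and 17.7 CPM, ORC6 was low with siL1 alone at 20.5 CPM, and ACLY stood at 601 and 633 CPM with the LSD1 siRNAs against 204 CPM in the control.

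The comparison of siL1 with the control asked which transcripts changed when LSD1 was depleted with the first siRNA. The membrane protein gene TMEM64 rose from 18.1 ± 0.221 to 111 ± 11.5 CPM (SD, n = 2 each; log2 fold change 2.62, adjusted p = 1.07e-10). GPR17, a G protein-coupled receptor, rose by 2.58 on the log2 scale, TMEM87B by 2.41, the phospholipid scramblase PLSCR4 by 2.37, the granzyme B inhibitor SERPINB9 by 2.23 and the calcium channel subunit CACNA2D1 by 2.09. RASGRF1, an exchange factor for Ras, rose by 1.94, the cytokine IL11 by 1.92, the secreted glycoprotein STC1 by 1.90 and the kinase UHMK1 by 1.89. Of these 10 genes, 7 carried TACATTT or ACATTTA in the 3' UTR. GPR17 and IL11 carried neither but held the hexamer ACATTT that both heptamers share, and RASGRF1 held none of these. ORC6, a subunit of the origin recognition complex, fell from 61.4 ± 3.11 to 20.5 ± 3.56 CPM (SD, n = 2 each; log2 fold change -1.58, adjusted p = 4.11e-08). Also lower were SLC35F3 of the solute carrier family (-1.42), the Golgi tether GCC2 (-1.36), the Rab GTPase-activating protein TBC1D10B (-1.31), the actin-binding XIRP2 (-1.29), the vasoactive peptide gene ADM (-1.25) and the splicing helicase DHX38 (-1.23). ORC6, SLC35F3, GCC2 and XIRP2 carried ACAGAGC in the 3' UTR.

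Genes of the cell cycle fell with siL1. Of 55 tested genes of G1/S and DNA replication, 44 fell and 3 rose, also when adjusted over the list alone (median log2 fold change -0.32). The list passed camera at adjusted p = 6.85e-08, and had adjusted p = 0.407 with an estimated correlation. The flap endonuclease FEN1 fell by 0.67 on the log2 scale, whereas the clamp loader subunit RFC5 rose by 0.73. Of 55 tested G2/M and mitosis genes, 38 fell and 3 rose, and 41 fell and 3 rose adjusted over the list alone (adjusted p = 4.87e-06, and adjusted p = 0.533 with an estimated correlation). The proliferation marker MKI67 fell from 622 ± 62.6 to 402 ± 13.0 CPM (SD, n = 2 each; log2 fold change -0.63, adjusted p = 1.09e-06). The cyclin-dependent kinase partner CKS2 (-0.56), the checkpoint kinase BUB1B (-0.48) and the mitotic kinase PLK1 (-0.39) fell. Of 10 tested replication-dependent histone genes, 5 fell and 0 rose, also when adjusted over the list alone (adjusted p = 0.0421, and adjusted p = 0.368 with an estimated correlation); HIST1H1C fell by 0.84.

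Genes of the extracellular matrix and its turnover rose with siL1. Of 42 tested matrix protein genes, 33 rose and 3 fell, also when adjusted over the list alone (median 0.47, adjusted p = 1.72e-07, and adjusted p = 0.334 with an estimated correlation). The fibrillar collagen COL5A1 rose by 1.70 on the log2 scale and FSTL1 by 0.92, whereas COL8A1 fell by 0.93. Of 30 TGF-beta and SMAD targets, 22 rose and 1 fell, also when adjusted over the list alone (adjusted p = 1.34e-05, and adjusted p = 0.368 with an estimated correlation). They included the receptor gene TGFBR1 (1.68) and LTBP2 (1.11). Of 29 matrix proteases and related genes, 19 rose and 3 fell, and 20 rose and 3 fell adjusted over the list alone (adjusted p = 4.5e-05, and adjusted p = 0.354 with an estimated correlation). The urokinase PLAU rose by 0.72, its receptor PLAUR by 0.91 and ADAM19 by 0.81. Of 14 protease inhibitors, 10 rose and 0 fell, also when adjusted over the list alone (adjusted p = 0.000937, and adjusted p = 0.334 with an estimated correlation), among them TIMP2 (0.89) and TIMP4 (1.45). Of 30 integrin and focal adhesion genes, 18 rose and 4 fell, and 19 rose and 4 fell adjusted over the list alone (adjusted p = 0.00327, and adjusted p = 0.538 with an estimated correlation). ITGAV rose by 1.02 and the tetraspanin CD151 by 0.73. TGFBR1, LTBP2, TIMP2 and ITGAV carried TACATTT or ACATTTA in the 3' UTR; PLAU and PLAUR did not. Markers of other cell types moved with these groups: 7 of 8 tested blood cell markers rose and 0 fell, also when adjusted over the list alone (adjusted p = 0.00556, and adjusted p = 0.354 with an estimated correlation). Of 8 fibroblast and endothelial markers, 6 rose and 0 fell, also when adjusted over the list alone (adjusted p = 0.00187, and adjusted p = 0.334 with an estimated correlation). PDGFRB stood at 0.83 CPM in the control and 7.22 CPM with siL1. The other members of these lists of 27 blood cell and 22 fibroblast and endothelial markers were below the count filter. Genes with a mean below 1 CPM leaned higher with siL1 in general (172 higher, 42 lower).

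Hypoxia and glycolysis genes also rose with siL1. Of 29 hypoxia genes, 19 rose and 2 fell, and 20 rose and 2 fell adjusted over the list alone (median 0.53, adjusted p = 1.34e-05, and adjusted p = 0.368 with an estimated correlation). The collagen lysyl hydroxylase PLOD2 rose by 1.05 and BNIP3L by 0.83, whereas the hypoxia-inducible ADM fell. Of 23 glycolysis and lactate genes, 17 rose and 1 fell, also when adjusted over the list alone (adjusted p = 0.000156, and adjusted p = 0.459 with an estimated correlation), with PFKFB4 at 1.13 and the lactate exporter SLC16A3 at 0.72. Of 26 YAP and TEAD targets, 15 rose and 7 fell, also when adjusted over the list alone (adjusted p = 0.0209, and adjusted p = 0.502 with an estimated correlation); CTGF rose by 0.94 and LATS2 by 1.16. Of 41 autophagy and lysosome genes, 21 rose and 5 fell, also when adjusted over the list alone (adjusted p = 0.0041, and adjusted p = 0.334 with an estimated correlation). Of 48 interferon response genes, 19 rose and 4 fell, also when adjusted over the list alone (adjusted p = 0.04, and adjusted p = 0.459 with an estimated correlation). Of 33 cholesterol biosynthesis genes, 15 rose and 5 fell, and 16 rose and 5 fell adjusted over the list alone (adjusted p = 0.0421, and adjusted p = 0.533 with an estimated correlation). Of 25 mesenchymal genes, 13 rose and 4 fell, and 13 rose and 6 fell adjusted over the list alone (adjusted p = 0.0494, and adjusted p = 0.533 with an estimated correlation).

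With siL1, 6712 genes passed the threshold, 3289 higher and 3423 lower than in the control, and of those changed at least 2-fold 500 were higher and 105 lower. Of 17 gene lists past the camera threshold, 14 were higher and 3 lower, and 0 passed with an estimated correlation. The calls of the cholesterol, mesenchymal, histone and interferon lists each ended without at least 1 library, at adjusted p from 0.0548 to 0.130, leaving 15 lists without either siL2 replicate, 16 without either control replicate or siL1 replicate 2, and 19 without siL1 replicate 1. Without genes holding 1 of the 3' UTR heptamers named here, a run chosen after seeing the data, the mesenchymal (adjusted p = 0.529), YAP (0.341), histone (0.0648) and interferon (0.0648) lists did not pass.

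The comparison of siL2 with the control asked the same of the second siRNA. PLSCR4 rose from 3.62 ± 0.087 to 22.2 ± 2.28 CPM (SD, n = 2 each; log2 fold change 2.62, adjusted p = 6.29e-09). TMEM87B rose by 2.25, TMEM64 by 2.23, GPR17 by 2.02, SERPINB9 and CACNA2D1 each by 1.93 and UHMK1 by 1.91. CCNG2, an atypical cyclin, rose by 1.81, KIAA1324 by 1.79 and the lipase LIPH by 1.70. Of these 10 genes, 8 carried TACATTT or ACATTTA in the 3' UTR. GPR17 carried only the hexamer ACATTT, and KIAA1324 none of these. SPNS2, a transporter of sphingosine-1-phosphate, fell from 98.5 ± 1.06 to 19.6 ± 2.30 CPM (SD, n = 2 each; log2 fold change -2.32, adjusted p = 2.11e-10). Also lower were ISOC1 (-2.21), the serine hydrolase RBBP9 (-2.18), the small GTPase RAB38 (-2.05) and the interstitial collagenase MMP1 (-1.95). The spermidine synthase SRM (-1.92), the RNA polymerase I subunit gene CD3EAP (-1.84), the signal recognition particle receptor SRPR (-1.79) and the Wnt receptor FZD5 (-1.76) fell as well. Of these 9 genes 8 had a 3' UTR in the reference, and 6 carried GTTACAA in it; SPNS2 and MMP1 did not.

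Cholesterol biosynthesis genes rose with siL2: of 33 tested, 25 rose and 2 fell, and 26 rose and 2 fell adjusted over the list alone. The median was 0.27 (adjusted p = 8.18e-06, and adjusted p = 0.545 with an estimated correlation). ACLY, which makes cytosolic acetyl-CoA, rose from 204 ± 9.40 to 633 ± 9.16 CPM (SD, n = 2 each), the methylsterol oxidase MSMO1 rose by 0.81, the sterol carrier STARD4 by 0.80 and the desaturase SCD by 0.46. ACLY carried a TACATTT or ACATTTA site in its 3' UTR. Cytosolic ribosomal protein genes fell: of 52 tested, 31 fell and 0 rose, and 36 fell and 0 rose adjusted over the list alone (median -0.12, adjusted p = 2.64e-05, and adjusted p = 0.822 with an estimated correlation). RPL6 (-0.66) and RPS3 (-0.32) fell. Of 48 interferon response genes, 20 rose and 2 fell, and 20 rose and 3 fell adjusted over the list alone (adjusted p = 0.0195, and adjusted p = 0.545 with an estimated correlation); SAMD9 rose by 1.07 and IFIT1 by 0.80. Of 41 autophagy and lysosome genes, 20 rose and 5 fell, and 20 rose and 6 fell adjusted over the list alone (adjusted p = 0.0195, and adjusted p = 0.545 with an estimated correlation), with GABARAPL1 at 1.35. Of 42 matrix protein genes, 20 rose and 6 fell, also when adjusted over the list alone (adjusted p = 0.0195, and adjusted p = 0.655 with an estimated correlation). COL5A1 rose by 0.64 and FSTL1 by 0.36. The blood cell markers (3 of 8 higher, 0 lower; 4 higher adjusted over the list alone) and the fibroblast and endothelial markers (6 of 8 higher, 0 lower, also when adjusted over the list alone) moved with the matrix genes. Their adjusted p were 0.0486 and 0.0345, and each had adjusted p = 0.545 with an estimated correlation.

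Further lists near the threshold with siL2 were matrix proteases (14 higher, 4 lower, also when adjusted over the list alone) and integrins (19 higher, 5 lower, also when adjusted over the list alone). TGF-beta targets had 13 higher and 5 lower, and 15 higher and 5 lower adjusted over the list alone. Replicative histone genes had 4 of 10 lower, and neuronal targets of REST and CoREST 8 of 20 lower and 3 higher, both also when adjusted over the list alone; SCG2 (-1.07) and GDAP1 (-0.72) fell. These 5 lists each had adjusted p = 0.0432. With an estimated correlation their adjusted p were 0.655 (proteases), 0.855 (integrins), 0.732 (TGF-beta), 0.545 (histones) and 0.655 (neuronal targets). Cell cycle genes did not pass the test with siL2: 17 G1/S genes were higher and 12 lower (adjusted p = 0.776), and 10 G2/M genes were higher and 12 lower (adjusted p = 0.966), also when adjusted over the list alone. MKI67 stood at 680 ± 0.479 CPM (SD, n = 2), with a log2 fold change of 0.13 (adjusted p = 0.0615). It passed with the replicate number as a block (adjusted p = 1.53e-05), DESeq2's size factors (0.0473), upper quartile scaling (0.0375), limma-voom (0.0449) and no filter (0.00964). Without control replicate 1 its log2 fold change was 0.24. Hypoxia genes (10 higher, 7 lower; 12 higher and 7 lower adjusted over the list alone; adjusted p = 0.776) and glycolysis genes (6 higher, 5 lower, also when adjusted over the list alone; adjusted p = 0.915) did not pass either.

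With siL2, 6106 genes passed the threshold, 3006 higher and 3100 lower, and of those changed at least 2-fold 287 were higher and 172 lower. Of 12 lists past the camera threshold, 9 were higher and 3 lower, and 0 passed with an estimated correlation. The calls of the cholesterol, ribosomal, interferon, autophagy and matrix protein lists held without any 1 library, and the other 7 each ended without at least 1, at adjusted p from 0.0509 to 0.144. The number of lists was 7 without control replicate 1, 8 without control replicate 2 or siL2 replicate 2, and 9 without each of the other libraries. Without genes holding 1 of the heptamers, a run chosen after seeing the data, only the cholesterol, autophagy and ribosomal lists passed; the matrix protein and interferon lists each had adjusted p = 0.106 there.

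**Figure D2:**
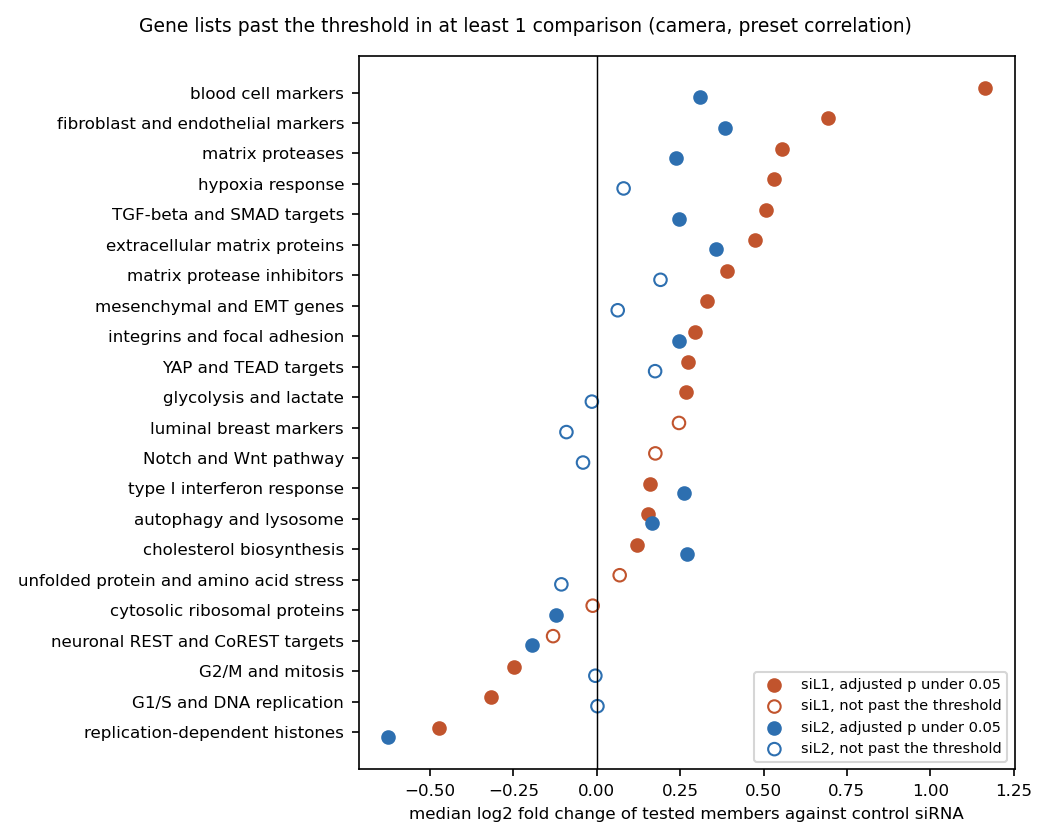
Median log2 fold change (horizontal axis) of the tested members of each gene list that passed the camera test with the preset correlation in at least 1 comparison (vertical axis), for siL1 (orange) and siL2 (blue) against the control; filled points passed for that siRNA and open points did not. Matrix protein genes stood at 0.47 and 0.36, G1/S genes at -0.32 with siL1, and cholesterol genes at 0.12 and 0.27.

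The mean of both siRNAs against the control asked how their average change ran, which a change with a single siRNA can also carry past the threshold. PLSCR4 rose by 2.5 on the log2 scale, TMEM64 by 2.43, TMEM87B by 2.33, GPR17 by 2.30, SERPINB9 by 2.08, CACNA2D1 by 2.01 and UHMK1 by 1.90. KIAA1324 rose by 1.78, the receptor kinase-like STYK1 by 1.75 and the p53-inducible TP53INP1 by 1.75. Of these 10 genes 7 carried TACATTT or ACATTTA, GPR17 and STYK1 only the hexamer ACATTT, and KIAA1324 none of these. Lower were SPNS2 (-1.75), ISOC1 and FZD5 (-1.42 each), the transcription factor gene ONECUT2 (-1.37), RBBP9 (-1.34), MMP1 (-1.3), ADM (-1.29), the Rap exchange factor RAPGEF5 (-1.17) and PODXL2 (-1.14). ISOC1, FZD5, ONECUT2 and RBBP9 carried GTTACAA. Matrix protein genes rose (28 of 42 higher, 4 lower; 29 higher and 4 lower adjusted over the list alone; adjusted p = 2.56e-05, and adjusted p = 0.333 with an estimated correlation). Cholesterol biosynthesis genes rose (21 of 33 higher, 1 lower; 21 higher and 2 lower adjusted over the list alone; adjusted p = 0.000273, and adjusted p = 0.333 with an estimated correlation). TGF-beta targets rose as well (19 of 30 higher, 2 lower; 20 higher and 2 lower adjusted over the list alone; adjusted p = 0.000337, and adjusted p = 0.370 with an estimated correlation). With the matrix genes moved the blood cell markers (adjusted p = 0.00372) and the fibroblast and endothelial markers (adjusted p = 0.00312), each with 6 of 8 higher and 0 lower, also when adjusted over the list alone. Both had adjusted p = 0.333 with an estimated correlation. G1/S genes passed in the mean (31 of 55 lower, 6 higher; 32 lower and 6 higher adjusted over the list alone; adjusted p = 0.000823, and adjusted p = 0.624 with an estimated correlation), although they did not with siL2 alone. G2/M genes did likewise (34 of 55 lower, 4 higher, also when adjusted over the list alone; adjusted p = 0.00288, and adjusted p = 0.686 with an estimated correlation).

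In this comparison 6562 genes passed the threshold, 3097 higher and 3465 lower, and of those changed at least 2-fold 311 were higher and 57 lower. Of 17 lists past the camera threshold 13 were higher and 4 lower, and 0 passed with an estimated correlation. The calls of the ribosomal and histone lists ended without control replicate 2 (adjusted p = 0.0609 and 0.0547), and that of the glycolysis list without control replicate 1 (adjusted p = 0.0561).

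Genes past the threshold with each siRNA overlapped. Higher with both were 1742 genes, where 742.1 would be shared by independent lists of those sizes, and lower with both were 1621, where 796.5 would be. The kinase UHMK1 (118, 440 and 446 CPM in the control, with siL1 and with siL2) and ADM (125, 52.4 and 50.1 CPM) are examples of either kind. UHMK1 carried both TACATTT and ACATTTA in the 3' UTR, and ADM neither. In opposite directions moved 243 genes that were higher with siL1 and lower with siL2 and 291 with the reverse, where 765.3 and 772.4 would be. Across the 13322 genes, which are not independent replicates, the log2 fold changes of both siRNAs had Pearson r = 0.560 and Spearman rho = 0.5. Both were measured against the same control libraries, and 20 simulations of unchanged groups against shared controls gave a mean r of 0.517 and a mean rho of 0.465. The covariance was 0.119, and 0.0133 in the simulations. In the simulations 0 genes passed with both siRNAs, in either direction. No gene was changed there, so this count is no baseline for the overlap between lists of 6712 and 6106 calls. With a control library of its own for each siRNA, a run chosen after seeing the data that gives fold changes only, r was 0.411 and 0.393 and the covariance 0.109 and 0.105 in the 2 possible assignments, across 13584 genes. The overlap of calls was not repeated this way, since each siRNA would have 1 control library, and part of its excess over independent lists may come from the shared controls. Both control libraries received the same control siRNA, so any effect of it stays in all these values. Of searched genes higher with both, 51.8% carried TACATTT or ACATTTA, against 32.9% of the others. For genes lower with both the shares were 28.5% and 36.8%. Without genes holding either heptamer, chosen after seeing the data, r against shared controls was 0.566.

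**Figure D3:**
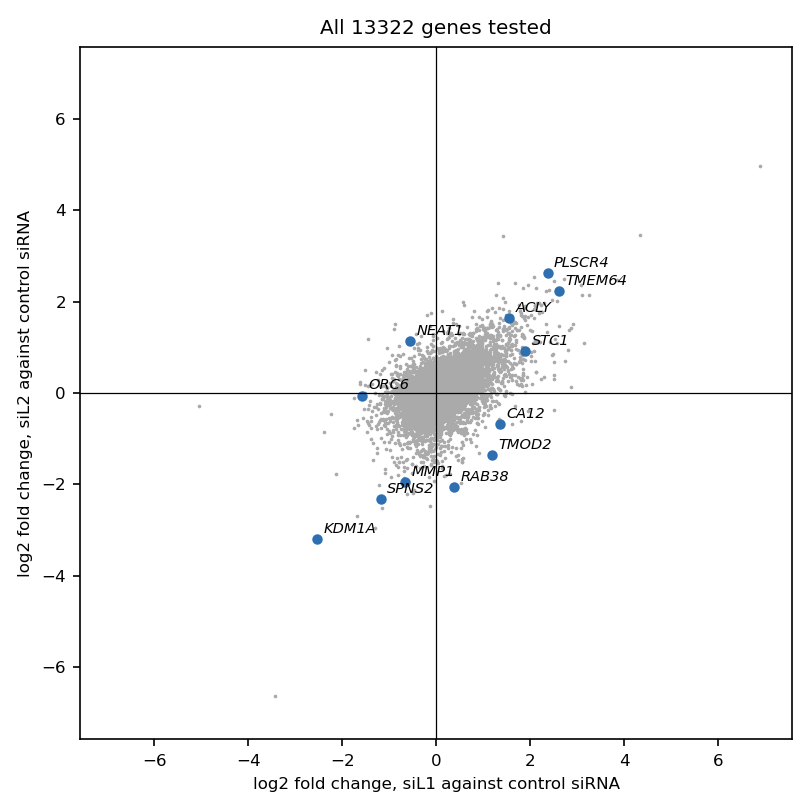
Log2 fold change against the control of each of 13322 genes with siL1 (horizontal axis) and siL2 (vertical axis); each point is a gene and the genes labelled are among those named in the text. The changes had Pearson r = 0.560 across genes; KDM1A stood at -2.53 and -3.19, whereas TMOD2 stood at 1.19 and -1.36.

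The direct comparison of siL2 with siL1 asked where the LSD1 siRNAs differed. RG9MTD2, a tRNA methyltransferase gene, was higher with siL2 (log2 difference 2.31, SE 0.118, adjusted p = 1.67e-08), with 7.08 CPM in the control, 3.79 with siL1 and 18.9 with siL2. LIPH (1.89), the anaphase-promoting complex subunit CDC26 (1.81), XIRP2 (1.76) and the paraspeckle RNA NEAT1 (1.69) were also higher with siL2. TMOD2, an actin-capping tropomodulin, was lower with siL2 (log2 difference -2.55, SE 0.131, adjusted p = 1.74e-08), with 6.22 CPM in the control, 14.2 with siL1 and 2.42 with siL2. RAB38 (-2.44), the carbonic anhydrase CA12 (-2.05), SRPR (-1.99) and the Ras effector RASSF5 (-1.97) were also lower with siL2. TMOD2, RAB38, CA12 and RASSF5 carried GTTACAA in the 3' UTR, and SRPR had none in the reference to search.

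Cell cycle genes were higher with siL2 than with siL1: 40 of 55 G1/S genes were higher and 2 lower, also when adjusted over the list alone (median 0.35, adjusted p = 1.51e-08, and adjusted p = 0.461 with an estimated correlation). For G2/M genes 40 of 55 were higher and 2 lower, also when adjusted over the list alone (adjusted p = 6.51e-07, and adjusted p = 0.627 with an estimated correlation). MKI67 differed by 0.76 and ORC6 by 1.52. Cholesterol genes were higher as well (20 of 33, 4 lower, also when adjusted over the list alone; adjusted p = 0.00208, and adjusted p = 0.461 with an estimated correlation). Lower with siL2 were hypoxia genes (20 of 29 lower, 1 higher; adjusted p = 6.51e-07), glycolysis genes (18 of 23 lower, 0 higher; adjusted p = 0.000136) and TGF-beta targets (15 of 30 lower, 2 higher; adjusted p = 0.00208). These counts were the same adjusted over the list alone, and each of these 3 lists had adjusted p = 0.461 with an estimated correlation. Matrix protein genes (22 of 42 lower, 5 higher; 24 lower and 5 higher adjusted over the list alone; adjusted p = 0.00161) and luminal breast markers (9 of 17 lower, 0 higher; 11 lower adjusted over the list alone; adjusted p = 0.000734) were lower with siL2 too. Both had adjusted p = 0.461 with an estimated correlation. Ribosomal protein genes were lower in 29 of 52 and higher in 1, and lower in 30 adjusted over the list alone (adjusted p = 0.000222, and adjusted p = 0.817 with an estimated correlation).

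Also lower with siL2 were Notch and Wnt pathway genes (16 of 40 lower, 5 higher; adjusted p = 0.00969), matrix proteases (15 of 29 lower, 3 higher; adjusted p = 0.0182) and unfolded protein response genes (13 of 33 lower, 4 higher; adjusted p = 0.0182). Protease inhibitors (7 of 14 lower, 1 higher; adjusted p = 0.0348) and fibroblast and endothelial markers (5 of 8 lower, 0 higher; adjusted p = 0.0488) followed. These 5 counts were the same adjusted over the list alone, and each list had adjusted p = 0.461 with an estimated correlation. In this comparison 6240 genes passed the threshold, 3088 higher and 3152 lower with siL2, and of those differing at least 2-fold 134 were higher and 342 lower. Of 14 lists past the camera threshold 0 passed with an estimated correlation. The calls ended for proteases and the unfolded protein response without siL1 replicate 2 (adjusted p = 0.0564 and 0.0608), for inhibitors without siL2 replicate 1 (adjusted p = 0.0757) and for fibroblast markers without siL2 replicate 2 (adjusted p = 0.0810). Without genes holding 1 of the heptamers, chosen after seeing the data, those of luminal markers (adjusted p = 0.0767), Notch and Wnt genes (0.0876), inhibitors (0.0717), the unfolded protein response (0.134) and fibroblast markers (0.0876) ended.

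Genes chosen by name for their place in invasion studies of LSD1 or ERR alpha moved in different ways. MMP1 stood at 11 ± 2.64, 6.99 ± 1.05 and 2.88 ± 0.918 CPM in the control, with siL1 and with siL2 (SD, n = 2 each). It fell with siL2 (log2 fold change -1.95, adjusted p = 1.05e-05) and passed the test at -0.66 with siL1 (adjusted p = 0.0104), where the call ended without control replicate 2 (-0.39, adjusted p = 0.144) or siL1 replicate 1 (-0.52, adjusted p = 0.0846). The authors' deposited adjusted p for MMP1 were 0.129 with siL1 and 6.04e-05 with siL2. ESRRA, which encodes ERR alpha, had log2 fold changes of 0.02 (adjusted p = 0.786) and 0.00 (adjusted p = 0.995). The EMT transcription factors SNAI1 (0.80 and 0.57) and SNAI2 (0.90 and 0.62) rose with siL1 and siL2, whereas ZEB1 did not pass (-0.09 and -0.07, adjusted p = 0.251 and 0.398); without siL2 replicate 1 it passed with siL2 (adjusted p = 0.0472). The p53 target CDKN1A rose by 0.90 and 0.51, and the interferon-induced IFIT1 by 0.42 and 0.80. In the 3' UTR SNAI1 and IFIT1 carried TACATTT or ACATTTA, and SNAI2 and CDKN1A the hexamer ACATTT without either heptamer. ZEB1 also carried ACATTTA, whereas MMP1, MMP9, ESRRA, VIM and MKI67 carried none of these. The intermediate filament gene VIM had -0.09 with siL1 (adjusted p = 0.0368, which did not pass with DESeq2's size factors at adjusted p = 0.0626) and 0.02 with siL2 (adjusted p = 0.611). The siL1 call of VIM also ended without control replicate 1 (adjusted p = 0.0767), control replicate 2 (adjusted p = 0.0801) or siL1 replicate 1 (adjusted p = 0.227). MMP9 had 0.218, 0.706 and 0.291 CPM, with a log2 fold change of 1.67 with siL1 (adjusted p = 0.00719) that did not pass without control replicate 1 (adjusted p = 0.0630) or siL1 replicate 2 (adjusted p = 0.0643). CDH1 was below the count filter and was not tested.

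Heptamers in 3' UTRs separated genes by group across the 10639 genes searched. Genes with GTTACAA, a heptamer that KDM1A mRNA also holds, were lower with siL2 than in the other groups (z = -19.8 over 1019 genes; the largest absolute z of 50 shuffles was 4.82). GTTACAA was in 57 of 109 genes at least 2-fold lower with siL2 (52.3%, Wilson 95% interval 43.0% to 61.4%) and in 962 of 10530 others (9.14%); the median 3' UTR length was 1669 bases in the former and 1432.5 in the latter. Genes with TACATTT or ACATTTA were lower with the control siRNA (z = -14.1 for each heptamer; largest shuffled 5.2). Either was in 58 of 94 genes at least 2-fold higher with both LSD1 siRNAs (61.7%, Wilson 95% interval 51.6% to 70.9%) and in 3735 of 10545 others (35.4%), with median 3' UTR lengths of 1893.5 and 1432 bases. Genes with ACAGAGC, also in KDM1A mRNA, were lower with siL1 (z = -8.42 over 1922 genes; largest shuffled 4.83). ACAGAGC was in 14 of 51 genes at least 2-fold lower with siL1 (27.5%, Wilson 95% interval 17.1% to 40.9%) and in 18.0% of the others, which lies inside that interval; it was in 21.1% of the genes at least 2-fold lower with siL2. Median 3' UTR lengths were 1516 and 1436.5 bases. The heptamers were picked on the same changes, so these shares describe the genes and are not tests. Of all heptamers scanned, 17.2% were in KDM1A mRNA.

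**Figure D4:**
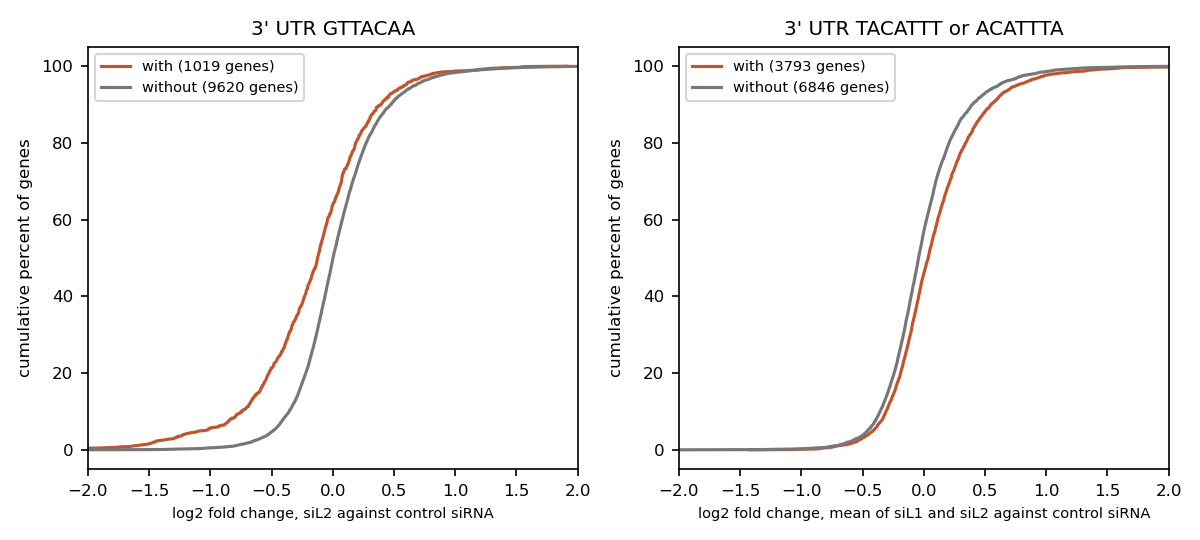
Cumulative percent of genes (vertical axis) by log2 fold change (horizontal axis), for genes with (orange) and without (grey) a 3' UTR heptamer: GTTACAA and the change with siL2 (left), and TACATTT or ACATTTA and the mean change of both LSD1 siRNAs (right). The curve of the 1019 genes with GTTACAA lay to the left of the others, and the curve of the genes with TACATTT or ACATTTA lay to the right.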

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

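The comparison with the extent of the knockdown and the heptamer scan without genes with an Alu core were chosen after the results were seen. The results in this part differed between siL1 and siL2 in the direct test (edgeR quasi-likelihood for genes, camera for lists, Benjamini-Hochberg adjusted). With an estimated correlation in camera 0 of the 14 lists passed, at adjusted p from 0.461 to 0.817. The list calls for proteases, their inhibitors, the unfolded protein response and fibroblast and endothelial markers each ended without 1 library. Of the genes tested, 534 passed the threshold in opposite directions with siL1 and siL2 and differed in the direct test.

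Among the genes named for a call in opposite directions, the log2 difference of siL2 minus siL1 was 2.31 for RG9MTD2, 1.81 for CDC26, 1.76 for XIRP2 and 1.69 for NEAT1, and -2.55 for TMOD2, -2.44 for RAB38, -2.05 for CA12, -1.99 for SRPR, -1.97 for RASSF5 and -1.61 for FERMT2. The calls of RAB38 and NEAT1 with siL1, and of XIRP2 with siL2, each ended without at least 1 library: RAB38 at adjusted p = 0.125 without control replicate 2, 0.0936 without siL1 replicate 1 and 0.0615 without siL1 replicate 2, NEAT1 at adjusted p = 0.0752 without control replicate 2 and 0.0723 without siL1 replicate 1, and XIRP2 at adjusted p = 0.0507 without control replicate 1 and 0.0653 without siL2 replicate 2. With DESeq2's Wald test the siL1 calls of RAB38 (adjusted p = 0.152) and NEAT1 (0.114) ended too. Among the genes chosen by name the difference was -0.66 for KDM1A, 0.76 for MKI67, -1.29 for MMP1, -1.27 for MMP9, -0.39 for CDKN1A, 0.38 for IFIT1 and 0.11 for VIM. The difference of MMP9 ended as a call without siL1 replicate 2 (adjusted p = 0.151), siL2 replicate 1 (0.0874) or siL2 replicate 2 (0.0920), and that of VIM without siL1 replicate 1 (0.108) or siL2 replicate 2 (0.140). Among the lists, the median difference was 0.35 for G1/S, 0.21 for G2/M and 0.26 for cholesterol biosynthesis genes. It was -0.43 for hypoxia, -0.25 for glycolysis, -0.29 for matrix proteins, -0.25 for matrix proteases, -0.38 for their inhibitors and -0.31 for TGF-beta targets. It was -0.14 for the unfolded protein response, -0.40 for luminal markers, -0.37 for fibroblast and endothelial markers, -0.26 for Notch and Wnt genes and -0.12 for ribosomal proteins.

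G1/S genes were lower with siL1 and not with siL2 by camera with the preset correlation. With an estimated correlation the list had adjusted p = 0.407 with siL1 and 0.461 for siL2 against siL1. A weaker knockdown by siL1 would put the larger change with siL2, where KDM1A was lower. The median siL2 minus siL1 difference of the 55 members was 0.35 (95% bootstrap interval 0.21 to 0.42), in the other direction. The list was picked for this pattern, so the difference restates it and is not a separate test. Direct repression of each gene through a siL1 seed site would spare members without the hexamers CAGAGC and AGAGCT of the leading siL1 heptamers, yet the 26 such members had a median siL1-specific change of -0.31 (interval -0.40 to -0.19), with 98.2% of the list searched. Still open are an effect of siL1 on a regulator of these genes, sites without these hexamers or outside 3' UTRs, and an effect of LSD1 loss that siL2 masks. No test here separates these.

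Genes with GTTACAA in the 3' UTR were lower with siL2 than in the other groups, and 52.3% of the genes at least 2-fold lower with siL2 carried it. If siL2 repressed other mRNAs through its seed, a heptamer found in KDM1A mRNA would mark such genes, and GTTACAA did (z = -19.8; -18.0 without genes with an Alu core). The same scan for siL1 gave ACAGAGC at z = -8.42, also in KDM1A mRNA (-7.73 without Alu genes). After ACAGAGC, the siL1 heptamers AGAGCGA (z = -7.08) and CAGAGCG (-6.95) were in KDM1A mRNA, but AAGAGCT (-7.12) and AGAGCTT (-6.40) were not. Without Alu genes ACAGAGC was followed by AAGAGCT (-7.05) and AGAGCTA (-6.90), neither in KDM1A mRNA, and by CAGAGCG (-6.58), which was. AGAGCGA was then not among the 6 lowest. ACAGAGC was in 27.5% of the genes at least 2-fold lower with siL1 (Wilson 95% interval 17.1% to 40.9%) and in 18.0% of the others. The latter share lies inside that interval. For siL2, TTACAAA (-10.8) was in KDM1A mRNA and TGTTACA (-8.92) was not. Seed off-targets are thus a hypothesis for siL2, with weaker ground for siL1, that the siRNA sequences would test directly. A microRNA or RNA-binding protein that reads the same sequence stays open.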

How the results depend on the processing

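The runs without genes holding a heptamer and with a control library of its own for each siRNA were chosen after seeing the data; the other alternatives were planned. KDM1A kept its direction and its call under every alternative run, from -2.56 to -2.50 with siL1, from -3.22 to -3.16 with siL2, from -2.89 to -2.83 for the mean and from -0.69 to -0.62 for siL2 against siL1. A required log2 change of at least 1 left 605 genes with siL1, 459 with siL2, 368 for the mean, 476 for siL2 against siL1 and 172 shared in direction; this follows from the stricter threshold. The other gene counts stayed within 1.5 times the reported ones; the lowest came from DESeq2's Wald test among runs on all libraries (5228, 4737, 5157, 4721 and 2499). Without 1 library, where the lone sample is assumed to vary like the other groups, siL1 gave 5452 to 6731 genes, siL2 4947 to 6060, the mean 5064 to 6244, siL2 against siL1 4944 to 6231, and the shared set 2632 to 3012. Similarity across genes ran from 0.501 to 0.640 without 1 library, and was 0.566 without genes holding a control heptamer and 0.411 and 0.393 with a control library of its own for each siRNA. No scaling moved the median of all genes by over 0.1.

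List calls depended on the test. With an estimated correlation in camera 0 lists passed in each comparison. With siL1 this held also for lists whose estimate lay below the preset 0.01. Among these were autophagy (correlation -0.00545, adjusted p = 0.334), protease inhibitors (-0.0644, 0.334) and fibroblast and endothelial markers (-0.0391, 0.334). A correlation between members above the preset therefore does not explain these losses, and other causes were not tested. The adjusted p with an estimated correlation is thus not a measure of how strongly the members of a list were correlated. With fry, which asks whether members move on balance one way, 30 passed with siL1, 23 with siL2 and 22 for siL2 against siL1; for either direction 37, 37, 37 (mean) and 36 passed. Without genes holding a heptamer, 3 lists passed with siL2 (cholesterol, autophagy and ribosomal); fewer genes were tested. Without 1 library 15 to 19 lists passed with siL1, 7 to 9 with siL2, 16 to 18 for the mean and 13 to 15 for siL2 against siL1.

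Of 10115 values over 184 named genes, 9875 kept their call or lack of a call, 151 ended the call and 89 gained one. Among values called in either run 0 reversed direction, and changes of sign among uncalled values were not counted. Of the lost calls 117 came without 1 library and 25 with DESeq2. ZEB1 gained its call in the mean without siL2 replicate 1 (adjusted p = 0.0362).

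The replicate numbers are not stated to share a day or batch and were treated as numbers only. As a block they gave 8036 genes with siL1, 7610 with siL2, 7963 for the mean, 7700 for siL2 against siL1 and 4401 shared, and, in the first 4 comparisons, 17, 10, 18 and 13 lists. With the block the neuronal (adjusted p = 0.0568) and blood cell (0.0679) lists did not pass with siL2, the mesenchymal list with siL1 (0.0978) or fibroblast markers for siL2 against siL1 (0.0536), and NF-kappaB cytokines passed with siL1 (0.0443) and in the mean (0.0451). MKI67 with siL2 (adjusted p = 1.53e-05) and ZEB1 with siL1 (0.0228) and in the mean (0.0191) passed with the block. Replicate differences correlated between groups at 0.133 to 0.198 over all genes and 0.349 to 0.453 at 5 CPM or more. Libraries of the same number thus shared part of their difference, which the main fit leaves in its spread. Depth limits genes with few counts: MMP9, with 0.218 to 0.706 CPM, lost its siL1 call without control replicate 1 (adjusted p = 0.0630) and with DESeq2 (adjusted p = 0.0980).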

Other observations

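The medians of matrix genes for each siRNA apart and the run without genes holding a heptamer were chosen after the results were seen. Of all genes tested, 50.4% passed the threshold with siL1 and 45.8% with siL2, and the list counts here and in the next paragraph are to be read beside these shares. Genes of chromatin regulation changed in both directions, as did the tested genes as a whole. Of 23 tested LSD1 complex partners 7 were higher and 8 lower with siL1, and 6 and 7 with siL2; of 22 histone demethylase genes 4 and 7, and 2 and 7; of 19 H3K4 and H3K9 methyltransferase genes 2 and 7, and 5 and 3. SETD7 rose by 0.99 and 0.79 on the log2 scale with siL1 and siL2 and the demethylase family gene PHF2 by 0.73 and 0.70, whereas KDM2B fell (-0.62 and -0.50). Of 14 RNA interference genes 4 were higher and 6 lower with siL1, and 2 and 5 with siL2, and DICER1 rose by 0.69 and 0.83. SETD7 and DICER1 carried TACATTT or ACATTTA. Expression also differed by level: of 1119 genes below 1 CPM 172 were higher and 42 lower with siL1, and 88 and 54 with siL2, and of 10448 genes at 5 CPM or more 2698 and 3224, and 2625 and 2871.

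In oxidative phosphorylation 4 of 47 genes were higher and 16 lower with siL1, and 6 and 10 with siL2; in the TCA cycle and fatty acid oxidation 8 and 14 of 45, and 9 and 12. TFAM, the mitochondrial transcription factor, fell by 1.47 with siL2 and carried GTTACAA. Further lists, as higher and lower with siL1 and then with siL2, were epithelial junctions (8 and 3, 5 and 4), MHC class I (8 and 2, 7 and 3), NF-kappaB cytokines (11 and 2, 8 and 4) and p53 targets (9 and 4, 10 and 7). Immediate early genes had 13 and 4, then 9 and 8, basal markers 7 and 1, then 6 and 2, luminal markers 8 and 1, then 2 and 7, apoptosis regulators 11 and 6, then 9 and 9, and NRF2 targets 11 and 3, then 9 and 6. Notch and Wnt genes had 14 and 6, then 8 and 10, and the unfolded protein response 11 and 8, then 3 and 12. With siL1 ribosomal proteins had 2 and 5 and neuronal targets 4 and 7; with siL2 protease inhibitors had 7 and 1, mesenchymal genes 10 and 4 and YAP targets 13 and 7. With the siRNA for which its counts are given in these sentences, no list passed camera with the preset correlation; the lowest adjusted p were 0.0562 with siL1 and 0.133 with siL2, and counts adjusted over the list alone differed by at most 3 in either direction.

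Of the genes past an adjusted p of 0.05 in the authors' deposited comparison, 4984 of 4989 with siL1 and 4501 of 4504 with siL2 were called in the same direction here, and 0 in the opposite direction.

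Genes with TACATTT or ACATTTA were lower in the control (z = -14.1), which a seed effect of the control siRNA could show as rises with both LSD1 siRNAs. Direct sites that hold the hexamer ACATTT predict no excess of rises among genes without it. Of 31 such genes changed at least 2-fold with both siRNAs, 28 were higher and 3 lower (90.3%, exact 95% interval 74.2% to 98.0%). Among all tested genes, also those below 1 CPM, 154 were higher and 18 lower (89.5%). Changes of at least 2-fold leaned higher at every level of expression, with 176 higher and 27 lower at 1 to 5 CPM with siL1. An even split is therefore not a sure baseline, and this excess cannot decide about direct control sites. Control heptamers that lack ACATTT also lay beyond the shuffles, such as CATTTAT (z = -9.00) and ATACATT (-7.85), so sites of that kind were not excluded. The 23 matrix protein genes without ACATTT had a median of 0.46 in the mean (interval 0.39 to 0.64), 0.60 with siL1 (0.37 to 0.94) and 0.36 with siL2 (0.11 to 0.55). Direct control sites with ACATTT are thus not enough for them, while control sites without it were not tested. The 18 without GTTACAA and ACAGAGC as well had 0.49 with siL1 (0.33 to 0.95) and 0.26 with siL2 (0.02 to 0.56, 13 above 0). By camera the matrix list without genes holding any of the heptamers did not pass with siL2 (22 members, adjusted p = 0.106). Blood cell markers (adjusted p = 0.00372) and fibroblast and endothelial markers (adjusted p = 0.00312) rose with the matrix genes in the mean; both had adjusted p = 0.333 with an estimated correlation. An effect of LSD1 loss, direct control sites without ACATTT, an indirect effect of the control siRNA, a microRNA that reads the same sequence and sites outside 3' UTRs stay open. Another control siRNA or a rescue with siRNA-resistant KDM1A would test them.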
